A study of Mus musculus with 14 samples.

How the data were processed

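RNA was measured in C2C12 cells, a mouse myoblast line, that carried a control short hairpin RNA (shControl) or one against Foxm1 (shFoxM1) and were quiescent or activated. Per the labels, total RNA was taken up in Trizol, libraries were made with the Illumina TruSeq RNA Sample Prep kit and sequenced on an Illumina HiSeq 2000. Groups were taken from the sample titles and labels, giving 3 libraries for each shControl group and 4 for each shFoxM1 group.

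The deposited table holds FPKM values (fragments per kilobase of transcript and per fixed number of mapped fragments), 1 column for each of the 14 libraries, with 2 decimals. Its name gives GENCODE gene models and RSEM. The submitters' processing notes name Bowtie 0.12.9, Cufflinks 2.1.1, HTSeq without a version and the mm10 build, and do not say which step made the values. The GENCODE release, any filter on reads and the use of strand in counting are not given in the sources used here. The table has 49585 genes, of which 25170 were at 0 in all libraries. Gene types, positions and lengths came from GENCODE release M21 on GRCm38, in which 49326 identifiers had a match without the version suffix and 259 had none.

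The columns sum to 2.74e+06 to 4.36e+06 FPKM, and 4 short RNAs (Rn7s1, Rn7s2, Rn7sk and Rmrp) made up 71.5 to 80.5% of each sum, so the sums are not depths. Depth was estimated from genes with a single transcript and low values, whose FPKM times length falls on steps of 1 read. This gave 2.66e+07 to 3.53e+07 reads per library, with 87.3 to 93.3% of the low values within 0.25 of a step. Counts per gene were not in the table, so no counting interval is given, and values near 0 rest on few reads.

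Values were transformed to log2(FPKM + 1). The 12432 genes with at least 1 FPKM in at least 3 libraries were tested with limma 3.58.1 in R 4.3.3 (1 model with 4 group means over the 14 libraries, empirical Bayes with a trend), with a Benjamini-Hochberg adjusted p below 0.05 over all genes tested. The comparisons were activated against quiescent cells in shControl and in shFoxM1 cells, shFoxM1 against shControl in quiescent and in activated cells, and the difference between the activation responses. For the 16 genes of main interest, exact permutation tests (two-sided, on the difference of mean log2 values) were run as well. With 3 against 3 libraries the smallest p these allow is 0.1, and with 4 against 3 it is 0.0286. Adjusted p-values in the text are limma's unless a set test is named.

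36 gene lists (pathways, complexes, markers of other cell types) were tested with camera in limma with a preset correlation of 0.01, for the 33 lists with at least 5 measured members, adjusted over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. The groups, comparisons, lists, thresholds and the rule for genes named in the text were fixed before the data were examined. The rule names 4 kinds of genes. They are the 16 genes of main interest, the 8 highest and 8 lowest log2 fold changes of a comparison, the 4 members of each list with the smallest p, and the 4 highest and 4 lowest lncRNA genes. The genes taken by fold change had to be called, reach 5 FPKM in the higher group (1 FPKM for lncRNA genes), keep the groups apart library by library and, lncRNA genes aside, carry a gene name. From these the text gives examples, and for the knockdown comparisons the lists whose members are named were chosen after their values were seen.

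The test was tried on 12432 simulated genes, 200 changed, 100 per fold. With noise built from the real residuals it recovered 58% of 2-fold and 95% of 4-fold changes on activation in shControl cells, 74 and 99% in shFoxM1 cells, 64 and 97% for the knockdown in quiescent cells, 73 and 98% in activated cells, and 27 and 84% for the difference between the responses. With 1 simulated list changed, camera called it alone of 33, but regrouped activated libraries gave up to 17.

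The alternatives were other pseudocounts and filters, rescaling every library to an equal sum, median-of-ratios scaling, quantile normalization, protein-coding genes alone, eBayes without trend or robust, array weights, a model of only the groups compared, shFoxM1 libraries 1 to 3 only, the replicate number as a block, stricter thresholds and leaving out each library in turn. Alternatives chosen after seeing the data were the removal of a smooth trend on GC content and transcript length (mgcv 1.9.3), alone and with the replicate block, scaling to the sum of protein-coding genes, leaving out single libraries for the lists, and a knockdown effect averaged over both states. No library or table column was left out. Sequence reads and differences in splicing were not analysed here.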

Results

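C2C12 cells are mouse myoblasts that divide in growth medium and can fuse into muscle fibres. Quiescent cells had been held in suspension in a semi-solid medium with methylcellulose, which arrests the cell cycle, and activated cells are so named by the labels, which do not say how they were activated. FoxM1, a forkhead transcription factor of dividing cells, was targeted with a short hairpin RNA. The 14 libraries are 3 of quiescent shControl cells, 4 of quiescent shFoxM1 cells, 3 of activated shControl cells and 4 of activated shFoxM1 cells, while the design text speaks of triplicates. The labels do not say whether the libraries of a group are separate cultures, so every p measures the spread between these libraries, which may be technical. FPKM values are means ± SD and log2 fold changes are given ± SE, with n = 3 for each shControl group and n = 4 for each shFoxM1 group.

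Estimated depth was 2.66e+07 to 3.53e+07 reads, with the highest value in quiescent shFoxM1 replicate 4. Between 11281 and 12046 genes reached 1 FPKM. Genes encoded in the mitochondrial genome made up 5.51 to 16.5% of the FPKM sum of protein-coding genes, lowest in quiescent shFoxM1 replicate 4 and highest in quiescent shFoxM1 replicate 3. The group medians of this share were 11.8% in quiescent shControl, 12.1% in quiescent shFoxM1, 8.82% in activated shControl and 8.18% in activated shFoxM1 cells. The first principal component held 52.8% of the variance and separated the quiescent from the activated libraries. The second held 14.7%, and its gene loadings followed GC content across genes (Spearman rho = -0.749, genes not being independent replicates). Quiescent shFoxM1 replicate 4 lay at the end of the second component.

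**Figure D1:**
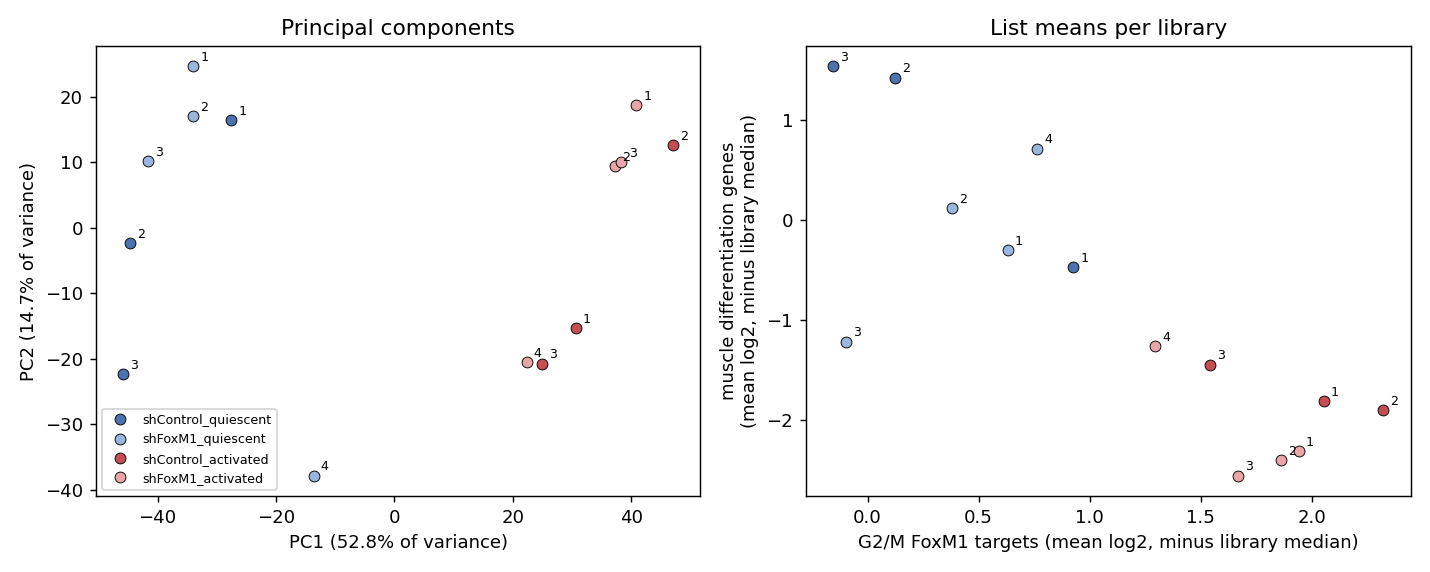
Each point is 1 of the 14 libraries, numbered by replicate and coloured by group; the left panel plots the first 2 principal components and the right panel the mean log2 value of 2 gene lists, each minus the library's median. All quiescent libraries lie at negative and all activated libraries at positive values of the first component, which holds 52.8% of the variance, and muscle differentiation means range from -1.22 to 1.53 in quiescent and from -2.56 to -1.27 in activated libraries.

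Foxm1 itself (ENSMUSG00000001517.14, GRCm38 chromosome 6, 128362967 to 128376146, plus strand) was at 35.8 ± 1.13 FPKM in activated shControl cells and at 17 ± 7.23 FPKM in activated shFoxM1 cells, a ratio of 0.475. In quiescent cells it was at 15.5 ± 7.34 FPKM with the control hairpin and 10.0 ± 3.93 FPKM with shFoxM1. Activated shFoxM1 replicate 3, at 27.58 FPKM, lay closer to the control libraries than replicates 1, 2 and 4, at 14.47, 14.74 and 11.21 FPKM. The log2 difference was -1.11 in activated cells (exact permutation p = 0.0571, limma p = 0.00328, adjusted 0.624). In quiescent cells it was -0.56 (0.229, 0.0973 and 1 in turn). Neither passed by exact or adjusted p, although in activated cells all 4 shFoxM1 libraries lay below all 3 control libraries. Leaving out 1 library moved the quiescent difference between -0.81 and -0.22, the latter without quiescent shControl replicate 1.

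**Figure D2:**
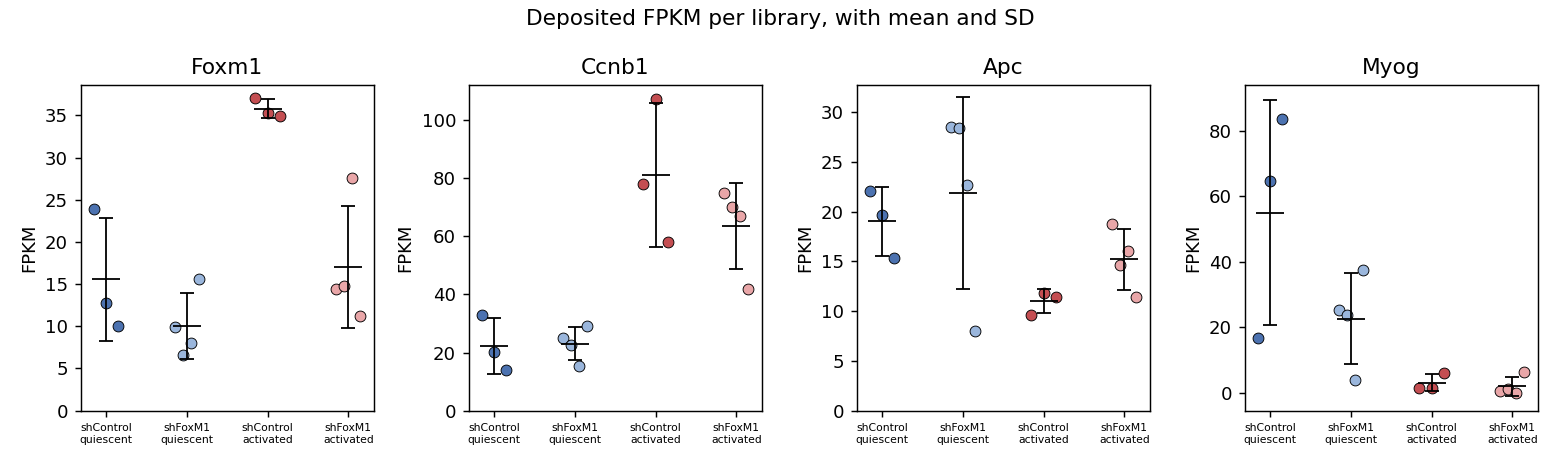
Points are the deposited FPKM of single libraries for Foxm1, Ccnb1, Apc and Myog in the 4 groups (n = 3 for shControl, n = 4 for shFoxM1), and lines and bars are the mean and SD. Foxm1 means are 15.5, 10.0, 35.8 and 17 FPKM from left to right, and Ccnb1 means are 22.4, 23.0, 81.2 and 63.5 FPKM.

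Activated shControl cells held more transcript of genes for mitosis and DNA replication than quiescent ones. Among known FoxM1 targets of the G2 and M phases, 33 of 36 measured members rose and 0 fell (36 and 0 adjusted over the list alone). Ccnb1, the cyclin partner of Cdk1 at entry into mitosis, went from 22.4 ± 9.68 to 81.2 ± 24.8 FPKM (log2 1.85 ± 0.31). Log2 fold changes were 1.75 ± 0.27 for the mitotic kinase Aurka, 1.58 for the kinase Plk1, 1.58 for Cdk1, 1.60 for the chromosomal passenger protein Cdca8 and 1.84 for Ube2c, the ubiquitin-conjugating enzyme of the anaphase-promoting complex. Foxm1 rose as well, by 1.24 ± 0.34 (adjusted p = 0.0146). In DNA replication, 36 of 40 measured members rose and 0 fell (38 and 0 adjusted over the list alone), with Mcm10, a factor of replication initiation, at 1.85 and Gins4, a subunit of the replicative helicase, at 0.87. In homologous recombination, 13 of 21 measured members rose and 0 fell (15 and 0 adjusted over the list alone), with the nuclease Exo1 at 1.69. Ccnd1, the cyclin of the G1 phase, rose by 1.69 ± 0.28. Mki67, a marker of dividing cells, had a log2 fold change of 1.22 that did not pass (adjusted p = 0.076). It passed without quiescent shControl replicate 1 (0.0125), with shFoxM1 libraries 1 to 3 only (0.0488), with the replicate block (0.0034), with median-of-ratios scaling (0.0442), with array weights (1.88e-06) and with the GC and length trend removed without (0.0108) and with the block (8.69e-04). The adjusted p of the genes that rose ranged from 3.89e-04 to 0.0146. Foxm1 no longer passed without quiescent shControl replicate 2 (adjusted p = 0.0592) or 3 (0.0648), or with libraries rescaled to equal sums (0.0904), a scaling that also ended the call of Gins4 (0.0609). The 3 lists were called by camera at the preset correlation (adjusted p = 1.47e-19, 5.65e-20 and 1.33e-08) and by fry (0.00201, 0.00149 and 0.00651), but not by camera with an estimated correlation (adjusted p = 0.208, 0.208 and 0.215).

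Some genes of ribosome biogenesis, cholesterol synthesis, oxidative phosphorylation and the integrated stress response were higher in activated shControl cells too. Of the ribosome biogenesis genes, 10 of 23 measured members rose and 0 fell (17 and 0 adjusted over the list alone), among them the nucleolar proteins Nop56 (1.13 ± 0.21), Npm1 (1.00 ± 0.27) and Fbl (0.84 ± 0.20). In cholesterol synthesis, 9 of 23 measured members rose and 0 fell (11 and 0 adjusted over the list alone), with Acat2 at 1.53 ± 0.38 and the prenyl transferase Fdps at 1.36. Among nuclear-encoded genes of oxidative phosphorylation, 12 of 32 measured members rose and 0 fell (15 and 0 adjusted over the list alone), with Cox5a, a subunit of cytochrome c oxidase, at 0.80. For the integrated stress response, 3 of 20 measured members rose and 0 fell (2 and 0 adjusted over the list alone), and 2 of those that rose, Psat1 (1.38) and Phgdh (1.57), encode enzymes of serine synthesis. The preset set test called these 4 lists (adjusted p = 6.93e-08, 1.37e-06, 6.78e-08 and 0.00433), none with the correlation estimated (adjusted p = 0.214, 0.357, 0.208 and 0.574), and fry called ribosome biogenesis (0.00605) and oxidative phosphorylation (0.00115) but not cholesterol synthesis (0.0539) or integrated stress (0.279). The integrated stress call ended without activated shControl replicate 3 (adjusted p = 0.409), where the list's median relative to all genes was 0.20 in place of 0.87, against 1.33 without activated shControl replicate 2. The oxidative phosphorylation call ended with quantile normalization (0.164). Rescaling to equal sums ended the calls of Nop56 (adjusted p = 0.0574), Fbl (0.147), Acat2 (0.0523), Fdps (0.0675), Cox5a (0.107) and Npm1 (0.174). Npm1 also failed without quiescent shControl replicate 3 (0.0548) or activated shControl replicate 2 (0.0602), with quantile normalization (0.196) and with protein-coding sum scaling (0.0553), and Fdps without quiescent shControl replicate 2 (0.0541) or activated shControl replicate 1 (0.0526).

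Muscle genes were lower in activated shControl cells, with a median of -2.62 relative to all genes. In muscle differentiation, 0 of 37 measured members rose and 35 fell (0 and 35 adjusted over the list alone). Myh3, the embryonic myosin heavy chain, went from 71.5 ± 51.5 to 0.433 ± 0.426 FPKM (log2 -5.21 ± 0.77), and Actc1, the cardiac actin that embryonic muscle also makes, fell by 4.76 on the log2 scale. The giant sarcomere protein Ttn (-4.48), the myosin light chain Mylpf (-4.09), nebulin (Neb, -3.19) and the calcium release channel Ryr1 (-2.45) fell too. Among myogenic regulators, 0 of 18 measured members rose and 11 fell (0 and 11 adjusted over the list alone). Myog, which drives myoblast differentiation, went from 55 ± 34.5 to 3.05 ± 2.63 FPKM (log2 -3.69 ± 0.80), and Myod1, the determination factor of the lineage, changed by -1.38 ± 0.34, while Myf5 had 0.31 (adjusted p = 0.541). The adjusted p of those that fell ranged from 1.55e-04 to 0.00843. Pax7, the marker of muscle stem cells, had group means of 0.01 to 0.0367 FPKM and was not tested. Both lists were called at the preset correlation (adjusted p = 5.61e-15 and 0.00195) and by fry (0.0015 and 4.22e-04) and neither by camera with an estimated correlation (0.214 and 0.208).

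Matrix and insulin and IGF signalling genes were lower in activated shControl cells. In the extracellular matrix list, 1 of 33 measured members rose and 29 fell (1 and 31 adjusted over the list alone), with the matrix protein periostin (Postn) going from 61.1 ± 16 to 0.82 ± 0.236 FPKM, the collagen Col12a1 at -3.43 ± 0.27, and the thrombospondins Thbs1 and Thbs2 at -2.91 and -1.77. In insulin and IGF signalling, 1 of 16 measured members rose and 12 fell (1 and 12 adjusted over the list alone), with the growth factors Igf2 and Igf1 at -4.46 ± 0.34 and -2.44 ± 0.22. Enpp2, which makes lysophosphatidic acid, was among the 8 lowest genes, at -4.11. Among integrins and adhesion genes, 1 of 19 measured members rose and 8 fell (1 and 9 adjusted over the list alone), with the collagen receptor Itga11 at -2.27 and Itgav at -1.14. In TGF-beta and BMP targets, 0 of 19 measured members rose and 8 fell (0 and 8 adjusted over the list alone), and in targets of YAP and SRF, 1 of 22 measured members rose and 10 fell (1 and 10 adjusted over the list alone). Each of the 5 lists passed at the preset correlation (adjusted p = 9.97e-18, 4.82e-05, 0.00337, 0.0087 and 0.0153) and by fry (2.90e-06, 5.70e-05, 4.40e-05, 0.00116 and 0.00608), and camera with an estimated correlation gave no call (adjusted p = 0.0711, 0.208, 0.208, 0.218 and 0.408). Without activated shControl replicate 3 the TGF-beta and YAP lists were no longer called (adjusted p = 0.112 and 0.0927), and without quiescent shControl replicate 1 the median of the TGF-beta list relative to all genes was -0.38 in place of -0.59.

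Signalling and quiescence genes also differed between the states of shControl cells. Among Wnt targets, 2 of 18 measured members rose and 11 fell (3 and 11 adjusted over the list alone), with the feedback inhibitors Axin2 (-1.49 ± 0.22) and Nkd2 (-2.84 ± 0.29), the ligand Bmp4 (-2.14) and Dkk3 (-1.84) lower. In the beta-catenin destruction complex, 0 of 12 measured members rose and 3 fell (0 and 3 adjusted over the list alone), and Apc, its scaffold, and beta-catenin (Ctnnb1) had -0.73 (adjusted p = 0.127) and -0.36 (0.23). Apc passed without quiescent shFoxM1 replicate 4 (0.00883), with shFoxM1 libraries 1 to 3 only (0.00474), with only the groups compared (0.0234), with the replicate block, alone (0.0285) or with the GC and length trend removed (0.0416), and Apc and Ctnnb1 passed with protein-coding sum scaling (0.0443 and 0.0257) and with array weights (9.45e-07 and 8.73e-06). In Notch targets, 0 of 9 measured members rose and 6 fell (0 and 7 adjusted over the list alone), with the receptor Notch3 at -2.33, Notch1 at -1.34 and the ligand Dll1 at -2.03. Of genes linked to satellite cell quiescence, 1 of 17 measured members rose and 9 fell (1 and 12 adjusted over the list alone), with the growth factor antagonist Spry1 at -1.88 and Rgs2, a regulator of G protein signalling, at -2.32. For immediate early genes, 1 of 21 measured members rose and 10 fell (1 and 11 adjusted over the list alone), with the nuclear receptor Nr4a1 at -1.62, the phosphatase Dusp1 at -1.42 and Fos at -1.36. In the interferon response, 0 of 18 measured members rose and 6 fell (0 and 6 adjusted over the list alone), with Ifit3 at -1.29 and the RNA sensor Ddx58 at -0.91. In the anaphase-promoting complex and its partners, 6 of 19 measured members rose and 1 fell (7 and 1 adjusted over the list alone), while its activator Fzr1 had 0.30 (adjusted p = 0.215) and passed with the GC and length trend removed (0.0103, and 0.0109 with the replicate block added) and with array weights (4.33e-07). The 6 lists other than the destruction complex passed at the preset correlation (adjusted p = 0.00589, 0.00178, 0.00158, 0.00433, 0.00402 and 0.00326) and by fry (4.22e-04, 2.42e-04, 2.97e-05, 2.62e-04, 0.00113 and 0.00153). None did with camera when the correlation was estimated (adjusted p = 0.214, 0.208, 0.0823, 0.208, 0.215 and 0.208). The destruction complex was called by fry (0.00153) and not by camera (adjusted p = 0.0588 at the preset correlation, 0.308 with it estimated). The median of the anaphase-promoting list relative to all genes was 0.47 without activated shControl replicate 3, in place of 0.30.

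Inhibitors of cyclin-dependent kinases and the retinoblastoma family moved in part. In the inhibitor list, 1 of 7 measured members rose and 3 fell (1 and 3 adjusted over the list alone) (adjusted p = 0.832 by camera at the preset correlation and 0.0249 by fry), with Cdkn1b (p27), which rises in resting cells, lower at -0.80 ± 0.17 and Cdkn1a (p21) at -0.31 (adjusted p = 0.579). Without activated shControl replicate 2 the log2 fold change of Cdkn1a was 0.0088 (adjusted p = 0.99), and only array weights called it (0.0238). The pocket proteins Rbl2 and Rb1 were lower, at -0.73 ± 0.21 and -0.81 ± 0.25 (adjusted p = 0.0199 and 0.0272). The Rbl2 call ended without quiescent shControl replicate 1 (0.0522) or 2 (0.0974) or activated shControl replicate 1 (0.0526) or 2 (0.0818). That of Rb1 ended without quiescent shControl replicate 1 (0.101) or 2 (0.0985) or activated shControl replicate 1 (0.0872) or 3 (0.0501), and with no filter on low values (0.0661). Among the 8 highest genes were the glutathione transferase Gsta1 (3.29 ± 0.58), the keratin Krt13 (2.88), the immune receptor Tigit (2.62) and the neurofilament Nefl (2.46).

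In total, limma called 3515 of 12432 genes between activated and quiescent shControl cells, 1460 higher and 2055 lower, of which 1270 changed at least 2-fold (471 higher, 799 lower). The groups did not overlap in 44.1% of genes, against 10% by chance. The count was 1896 without quiescent shControl replicate 2 and 2196 without activated shControl replicate 2, and 4341 without quiescent shFoxM1 replicate 4. The balance of directions depended on scaling, with 41.5% of calls higher as deposited, 54.5% with median-of-ratios scaling, 54.3% with quantile normalization, 53.5% with the GC and length trend removed, 11.4% rescaled to equal sums and 14.6% with protein-coding sum scaling. The median log2 fold change of all genes was -0.11, and it was -0.26 rescaled to equal sums and -0.36 with protein-coding sum scaling.

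In shFoxM1 cells, activation was also accompanied by higher mitotic and replication transcripts. Of the G2 and M phase targets, 31 of 36 measured members rose and 0 fell (36 and 0 adjusted over the list alone), with Ccnb1 going from 23 ± 5.69 to 63.5 ± 14.7 FPKM (log2 1.42 ± 0.27). The kinases Aurka (1.63 ± 0.23), Plk1 (1.45) and Cdk1 (1.40), the chromosomal passenger proteins Cdca8 (1.46) and survivin (Birc5, 1.57) and Ube2c (1.68) rose. In DNA replication, 38 of 40 measured members rose and 0 fell (39 and 0 adjusted over the list alone), with Mcm10 at 1.60, Gins4 at 0.84, the polymerase subunit Pola2 at 1.33 and the helicase subunit Mcm7 at 1.31. In homologous recombination, 18 of 21 measured members rose and 0 fell (20 and 0 adjusted over the list alone), with Exo1 at 1.63. Ccnd1 rose by 1.94 ± 0.24, and adjusted p for the named genes that rose ranged from 1.11e-04 to 0.00221. Foxm1 had 0.69 ± 0.29 and did not pass (adjusted p = 0.0861), but did without quiescent shFoxM1 replicate 4 (0.0228) or activated shFoxM1 replicate 4 (0.0464), with shFoxM1 libraries 1 to 3 only (0.0108) and with array weights (0.00118). Mki67 had 0.97 (adjusted p = 0.102) and passed without activated shFoxM1 replicate 4 (0.04), with the replicate block (0.00469), with array weights (0.00781) and with the GC and length trend removed without (0.031) and with the block (0.0019). All 3 lists were called at the preset correlation (adjusted p = 9.66e-14, 2.29e-16 and 3.71e-08) and by fry (0.00292, 0.00116 and 0.00258), none by camera with an estimated correlation (adjusted p = 0.278, 0.278 and 0.278).

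Genes of cholesterol synthesis and ribosome biogenesis were higher in activated shFoxM1 cells, as were some of oxidative phosphorylation, glycolysis and the integrated stress response. In cholesterol synthesis, 21 of 23 measured members rose and 0 fell (21 and 0 adjusted over the list alone), with the epoxidase Sqle at 1.65 ± 0.29 and Acat2 at 1.80. In ribosome biogenesis, 19 of 23 measured members rose and 0 fell (23 and 0 adjusted over the list alone), with Nop56 at 1.14, Fbl at 1.03 and the RNA methyltransferase Nop2 at 1.04. For oxidative phosphorylation, 10 of 32 measured members rose and 1 fell (10 and 1 adjusted over the list alone), for glycolysis, 7 of 17 measured members rose and 2 fell (7 and 2 adjusted over the list alone), and for the integrated stress response, 5 of 20 measured members rose and 0 fell (6 and 1 adjusted over the list alone), with Psat1 at 1.59 and Phgdh at 1.65. The preset set test called these lists (adjusted p = 1.45e-08, 5.08e-09, 0.0113, 0.0392 and 0.0181), and none was called with the correlation estimated (adjusted p = 0.342, 0.278, 0.495, 0.516 and 0.636). Fry called the first 4 (0.00652, 0.00116, 0.0119 and 0.0476) and not integrated stress (0.141). The oxidative phosphorylation call ended without quiescent shFoxM1 replicate 2 (adjusted p = 0.0867), and its median relative to all genes, 0.21, was 0.13 without quiescent shFoxM1 replicate 1, 0.14 without activated shFoxM1 replicate 4 and -0.042 with quantile normalization. The glycolysis call ended without quiescent shFoxM1 replicate 1 (0.117) or 2 (0.094) or activated shFoxM1 replicate 3 (0.118) or 4 (0.0569), and in 3 other settings, and the integrated stress call without activated shFoxM1 replicate 4 (0.165).

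Muscle, matrix and insulin/IGF genes were lower in activated shFoxM1 cells. In muscle differentiation, 0 of 37 measured members rose and 30 fell (0 and 33 adjusted over the list alone), with Ttn at -3.47 ± 0.52, the troponins Tnnt1 and Tnnt3 at -3.35 and -3.14, and Ryr1 at -1.71. Among myogenic regulators, 0 of 18 measured members rose and 10 fell (0 and 10 adjusted over the list alone), with Myog going from 22.6 ± 13.8 to 1.97 ± 2.93 FPKM (log2 -3.10 ± 0.69), Myod1 at -1.86 and Myf5 at -0.31 (adjusted p = 0.481), the last of which was 0.10 without activated shFoxM1 replicate 3. The exact permutation p of Myog was 0.0571. Its groups overlapped, with quiescent shFoxM1 replicate 3 at 3.95 and activated shFoxM1 replicate 4 at 6.33 FPKM. In the extracellular matrix list, 1 of 33 measured members rose and 27 fell (1 and 27 adjusted over the list alone), with Postn at -3.99, Col12a1 at -3.63, Col6a2 at -3.58, the proteoglycan decorin (Dcn) at -3.12 and Thbs1 at -2.23. In insulin and IGF signalling, 1 of 16 measured members rose and 11 fell (1 and 12 adjusted over the list alone), with Igf2 at -3.86 ± 0.30, Igf1 at -1.75 and the adaptor Irs1 at -1.50. In TGF-beta and BMP targets, 0 of 19 measured members rose and 4 fell (0 and 4 adjusted over the list alone). Enpp2 (-4.65), Nrep (-3.70) and Islr (-3.86) were among the 8 lowest genes. At the preset correlation the 5 lists were called (adjusted p = 9.68e-14, 1.99e-04, 3.88e-16, 3.55e-06 and 0.045) and by fry (0.00652, 0.00116, 1.53e-05, 1.78e-04 and 0.0159), but by camera with the correlation estimated none was (adjusted p = 0.278, 0.269, 0.0716, 0.141 and 0.425). The TGF-beta call ended without quiescent shFoxM1 replicate 1 (0.0605) or 4 (0.121) or activated shFoxM1 replicate 4 (0.216), and in 5 other settings including the replicate block (0.0733), and its median relative to all genes was -0.43 without activated shFoxM1 replicate 3 in place of -0.28.

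Among signalling genes of shFoxM1 cells, more Wnt targets were lower than higher on activation, as 3 of 18 measured members rose and 9 fell (4 and 10 adjusted over the list alone), with Axin2 at -1.80 ± 0.19, Nkd2 at -2.86 and Bmp4 at -2.18. Lgr6, the stem cell receptor for R-spondins, rose by 2.43. In the destruction complex, 1 of 12 measured members rose and 2 fell (1 and 2 adjusted over the list alone) (adjusted p = 0.218 by camera at the preset correlation and 0.0476 by fry), with Apc at -0.37 (adjusted p = 0.375) and Ctnnb1 at -0.18 (0.49), and Apc reached -0.78 (0.00343) without quiescent shFoxM1 replicate 4 and also passed with shFoxM1 libraries 1 to 3 only (0.00734) and with array weights (9.08e-04). In Notch targets, 1 of 9 measured members rose and 5 fell (1 and 6 adjusted over the list alone), with Notch3 at -2.17 and Dll1 at -1.89, and in the satellite cell quiescence list, 2 of 17 measured members rose and 9 fell (3 and 10 adjusted over the list alone), with Spry1 at -1.64, Rgs2 at -2.59 and the surface protein Cd34 at 1.84. In the interferon response, 0 of 18 measured members rose and 7 fell (0 and 8 adjusted over the list alone), and in the anaphase-promoting complex, 7 of 19 measured members rose and 0 fell (7 and 1 adjusted over the list alone). Its activator Fzr1 had 0.39 (adjusted p = 0.0718) and passed without quiescent shFoxM1 replicate 4 (0.0317), activated shControl replicate 1 (0.0448) or 2 (0.0421), with shFoxM1 libraries 1 to 3 only (0.0459), with array weights (0.0011), or with the GC and length trend removed, alone (0.0182) or with the replicate block (0.0181). Cdkn1b was at -0.86 ± 0.15, Rbl2 at -0.73 ± 0.18, which did not pass rescaled to equal sums (0.0805), and Cdkn1a at 0.20 (adjusted p = 0.696). The preset set test called the Wnt, Notch, quiescence, interferon and anaphase-promoting lists (adjusted p = 0.0113, 0.0072, 0.00105, 1.87e-04 and 0.0139), as did fry (0.00258, 0.00181, 9.29e-05, 0.00123 and 0.00116), and camera with the correlation estimated called none (adjusted p = 0.278, 0.278, 0.0716, 0.278 and 0.278). The Wnt call ended without quiescent shFoxM1 replicate 4 (adjusted p = 0.0783) and with protein-coding sum scaling (0.0689), the Wnt and Notch calls with shFoxM1 libraries 1 to 3 only (0.116 and 0.0577), and the anaphase-promoting call with quantile normalization (0.057). Not called at the preset correlation were immediate early genes (2 rose and 5 fell of 21 (3 and 7 adjusted over the list alone); adjusted p = 0.21), integrins and adhesion (2 rose and 5 fell of 19 (2 and 5 adjusted over the list alone); 0.186, and 0.0364 by fry), where the laminin receptor Itga6 had 1.81 and Itga11 -1.28, and YAP and SRF targets (4 rose and 6 fell of 22 (4 and 6 adjusted over the list alone); 0.249). Among the 8 highest genes were Tigit (3.05), Nefl (2.53), the AP-1 member Fosl1 (2.28), Nptx1 (2.37) and the integrin Itgb7 (2.29).

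Over all genes, limma called 3814 of 12432 between activated and quiescent shFoxM1 cells, 2279 higher and 1535 lower, of which 1075 changed at least 2-fold (541 higher, 534 lower). The groups did not overlap in 27.8% of genes, against 2.86% by chance. The count lay between 2714 without quiescent shFoxM1 replicate 3 and 4896 without quiescent shFoxM1 replicate 4. Of the calls, 59.8% were higher as deposited, 69.4% rescaled to equal sums and 29.1% with protein-coding sum scaling, which moved the median log2 fold change of all genes from 0.03 to -0.19.

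**Figure D3:**
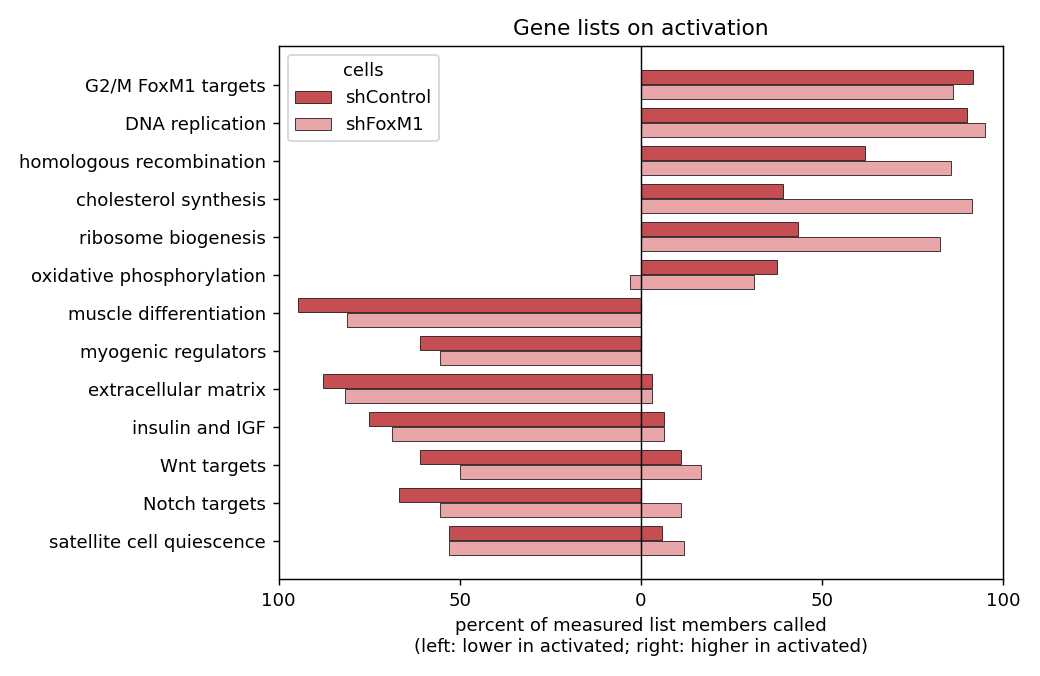
Bars give the percent of measured members of 13 gene lists that were called higher (right) or lower (left) on activation in shControl (dark) and shFoxM1 (light) cells. In muscle differentiation 35 of 37 members fell in shControl and 30 of 37 in shFoxM1 cells, and in DNA replication 36 and 38 of 40 rose.

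Most genes moved the same way on activation in both kinds of cells. Of the 1460 genes higher in shControl and the 2279 higher in shFoxM1 cells, 1270 were shared, against 267.6 for independent sets. Of the 2055 and 1535 lower genes, 1270 were shared as well, against 253.7. No gene called in both moved in opposite directions. Across the 12432 genes the responses had r = 0.894, and genes are not independent replicates. Shared genes include Ccnb1, Aurka, Plk1, Mcm10, Psat1 and Ccnd1 among the higher and Myog, Myod1, Ttn, Postn, Col12a1, Igf2, Axin2, Notch3 and Cdkn1b among the lower. Rescaling to equal sums left 299 shared higher and 808 shared lower genes.

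In quiescent cells, mean values of muscle genes were lower with shFoxM1, but no gene passed the test. Myh3 was at 71.5 ± 51.5 FPKM in shControl and 14.2 ± 12 FPKM in shFoxM1 cells (log2 -2.20 ± 0.72, adjusted p = 1), and the muscle genes Myh1, a fast myosin heavy chain, Neb and the myosin chaperone Unc45b had -1.21, -1.53 and -1.12. Myog was at 55 ± 34.5 and 22.6 ± 13.8 FPKM (log2 -1.30, exact permutation p = 0.229). Itga11, an integrin that binds collagen, had the smallest adjusted p, 0.179, at 3.98 ± 0.288 and 1.52 ± 0.44 FPKM (log2 -0.99 ± 0.16). No cell cycle gene named here passed, with Ccnb1 at 0.088 (exact permutation p = 0.771), Plk1 at 0.18 (0.686), Cdk1 at 0.049 (0.886), Mki67 at 0.21 (0.743) and Ccnd1 at 0.29 (0.429). Leaving out 1 library moved these values or turned their sign. Without quiescent shControl replicate 1, Ccnb1, Plk1 and Mki67 were 0.40, 0.51 and 0.79, without replicate 3 of that group Ccnb1, Plk1, Cdk1 and Mki67 were -0.19, -0.051, -0.075 and -0.22, without quiescent shFoxM1 replicate 4 Ccnb1, Plk1 and Cdk1 were -0.032, -0.089 and -0.15, and without quiescent shFoxM1 replicate 1 Mki67 was -0.053. Mki67 passed with array weights alone (0.0271). In the exact permutation test, p was 1 for Fzr1 (-0.0037), 0.943 for Apc (0.064), 0.571 for Ctnnb1 (0.056), 0.714 for Axin2 (0.082), 0.486 for Cdkn1a (-0.34), 0.771 for Cdkn1b (-0.032), 0.6 for Myod1 (-0.20) and 0.2 for Myf5 (0.39).

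The preset set test called 8 lists for shFoxM1 in quiescent cells, and medians are given relative to all genes. Lower were muscle differentiation (-1.10; adjusted p = 3.98e-28; 3 members fell adjusted over the list alone), extracellular matrix (-0.23; 1.63e-09), immediate early genes (-0.24; 6.29e-07), the interferon response (-0.17; 4.84e-04), integrins and adhesion (-0.13; 0.00147; 1 fell over the list alone) and Notch targets (-0.18; 0.0265). DNA replication (0.14; 6.41e-04) and G2 and M phase targets (0.11; 0.043) were higher. In the order named, all calls were lost when the correlation was estimated (adjusted p = 0.209, 0.209, 0.0669, 0.29, 0.209, 0.427, 0.898 and 0.925), and fry called 0 lists. Immediate early members included Egr3 (-0.72), Fos (-0.66), Zfp36 (-0.31) and Ier2 (-0.51). Wnt targets (-0.018; adjusted p = 0.711) and the beta-catenin destruction complex (-0.045; 0.711) were not called. Without quiescent shFoxM1 replicate 4 the DNA replication and G2 and M medians were -0.029 and -0.045 and neither was called (adjusted p = 0.926 and 0.716). Quiescent shControl replicate 3 ended the calls of G2 and M targets (0.0892), DNA replication (0.383), interferon (0.338) and Notch (0.116) when left out, and quiescent shControl replicate 2 those of G2 and M targets (0.621), DNA replication (0.0774) and Notch (0.0994). The G2 and M call also ended without quiescent shFoxM1 replicate 1 (0.391), and the Notch call without quiescent shFoxM1 replicate 2 (0.108) or 3 (0.0677). The muscle median was -0.71 without quiescent shControl replicate 2, -0.69 without replicate 3 of that group and -0.68 without quiescent shFoxM1 replicate 3.

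Across genes, limma called 0 of 12432 for shFoxM1 in quiescent cells, with 263 at an unadjusted p under 0.05 where 622 are expected by chance. That count was 453 with the replicate block, 649 with shFoxM1 libraries 1 to 3 only, 620 without quiescent shFoxM1 replicate 4, 515, 146 and 108 without quiescent shControl replicates 1, 2 and 3, and 4506 with array weights. The groups did not overlap in 3.12% of genes, against 5.71% by chance. Without quiescent shControl replicate 1, 19 genes were called, all lower, among them the muscle list members Cacna1s, Neb, Unc45b, Casq2, Myh1, Klhl41 and Myom1, and without quiescent shControl replicate 2 the calls were Gm26917 (-3.12) and Gm42418 (-3.08). With no filter on low values 4 genes were called: Itga11 (adjusted p = 0.0449), Trbv7 (-0.49), Myo7a (-0.30) and Acpp (-0.53), chosen for mention after their values were seen. Array weights called 2564 genes with 1 library holding most of the weight.

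In activated cells, shFoxM1 libraries held less Foxm1 by value, and none of its target genes of the G2 and M phases passed the test. Ccnb1 was at 81.2 ± 24.8 FPKM in shControl and 63.5 ± 14.7 FPKM in shFoxM1 cells (log2 -0.34, exact permutation p = 0.371). The targets with the smallest p were the kinetochore protein Cenpf (-0.75 ± 0.36), the phosphatase Cdc25b (-0.37), the centromere histone Cenpa (-0.36) and Ccnb2 (-0.36), with adjusted p of 0.632 to 0.702. Exact permutation p was 0.829 for Plk1 (0.053), 0.743 for Cdk1 (-0.13), 0.971 for Mki67 (-0.044) and 0.114 for Ccnd1 (0.54). For Apc it was 0.114 (0.42), for Ctnnb1 0.4 (0.23), for Axin2 0.314 (-0.23) and for Fzr1 0.743 (0.081), all by the exact test. Myod1 had -0.68 (exact permutation p = 0.171), Myog -0.70 (0.429), Myf5 -0.23 (1), Cdkn1a 0.17 (0.657) and Cdkn1b -0.092 (0.4). The adhesion genes Itgav (25.3 ± 0.816 and 38.9 ± 5.72 FPKM, log2 0.59 ± 0.16), Actn1 (0.50), Itga5 (0.38) and Vcl (0.40) were higher by value with adjusted p of 0.624 to 0.632. The respiratory chain genes Ndufa1 (-0.39), Cox7c (-0.35), Ndufa2 (-0.27) and Ndufv2 (-0.26) were lower by value, at 0.624 to 0.633.

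The preset set test called 7 lists for shFoxM1 in activated cells, where the median log2 fold change of all genes was 0.11 and list medians are relative to it. Oxidative phosphorylation (-0.27; adjusted p = 3.54e-10), the interferon response (-0.25; 2.57e-04), G2 and M phase targets (-0.21; 2.57e-04), muscle differentiation (-0.27; 3.46e-04) and mitochondrially encoded genes (-0.35; 0.00482) were lower. Integrins and adhesion (0.17; 0.0104; 2 rose adjusted over the list alone) and the unfolded protein response (0.19; 0.0104) were higher. In that order the calls were lost when the correlation was estimated (adjusted p = 0.475, 0.475, 0.759, 0.759, 0.759, 0.475 and 0.759), and fry called 0 lists. The G2 and M call ended without activated shControl replicate 2 (0.228) or activated shFoxM1 replicate 4 (0.0588). The mitochondrial call ended without the same libraries (0.319 and 0.0597), with the replicate block (0.354) and with quantile normalization (0.829). The adhesion call ended without activated shControl replicate 2 (0.0826) or 3 (0.0838), the unfolded protein call without activated shControl replicate 3 (0.0928) or activated shFoxM1 replicate 3 (0.364), and the muscle call with median-of-ratios scaling (0.0865). Not called were DNA replication (-0.045; adjusted p = 0.381; its median not taken relative to all genes was 0.07), Wnt targets (0.049; 0.421; 3 rose adjusted over the list alone) and the destruction complex (0.053; 0.381). Outside the called lists, 2 YAP and SRF targets and 1 hypoxia gene also rose adjusted over the list alone.

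Across genes, limma called 0 of 12432 for shFoxM1 in activated cells, with 978 at an unadjusted p under 0.05 where 622 are expected by chance, and 0 without any single library. The unadjusted count depended on the setting, with 5097 rescaled to equal sums (smallest adjusted p 0.0694), where the median of all genes was 0.39 in place of 0.11, 1813 with the replicate block, 1665 with shFoxM1 libraries 1 to 3 only, 1566 with protein-coding sum scaling, 645 with quantile normalization, 6133 with array weights, and 544 and 1847 without activated shControl replicates 1 and 3. The smallest adjusted p was 0.624, and the groups did not overlap in 9.40% of genes, against 5.71% by chance. With no filter on low values 1 gene was called, Gm15596 (-0.080, adjusted p = 0.0076), named here after its value was seen, and array weights called 4896. No calls could be shared between the knockdown in quiescent and activated cells, and across the 12432 genes these log2 fold changes had r = 0.174 with the same sign in 51.9%. Averaged over both states, a contrast added after seeing the data, limma called 0 genes, with 614 at an unadjusted p under 0.05, and 1604 with the replicate block (smallest adjusted p 0.0601), 2178 rescaled to equal sums, 1845 with shFoxM1 libraries 1 to 3 only, 1431 without quiescent shFoxM1 replicate 4, 1011 without activated shControl replicate 3, 941 and 269 without quiescent shControl replicates 1 and 3 and 374 without activated shControl replicate 1. Without quiescent shControl replicate 1, 9 genes were called.

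The activation response with and without shFoxM1 was compared gene by gene as an interaction. Among integrins and adhesion genes, the log2 fold change in shFoxM1 cells minus that in shControl cells was 0.99 ± 0.22 for Itga11, 0.78 ± 0.22 for Itgav, 0.74 for Itga5 and 0.51 for the actin crosslinker Actn1. For the immediate early genes it was 0.83 for Nr4a1, 1.07 for Egr3, 0.81 for Fos and 0.70 for Ier3. None of these passed, and the adjusted p of all was 0.993. Foxm1 had -0.55 ± 0.45, Ccnb1 -0.43, Plk1 -0.13, Cdk1 -0.18, Mki67 -0.26 and Ccnd1 0.25. Fzr1 was at 0.085, Apc at 0.36, Ctnnb1 at 0.17, Axin2 at -0.31, Cdkn1a at 0.50, Cdkn1b at -0.060, Myod1 at -0.48, Myf5 at -0.62 and Myog at 0.60. In total limma called 0 of 12432 genes, with 433 at an unadjusted p under 0.05 where 622 are expected by chance. That count was 1804 rescaled to equal sums, 269 with median-of-ratios scaling, 1100 without activated shControl replicate 3, 247 without quiescent shControl replicate 2 and 4685 with array weights.

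For the difference between responses, the preset set test called 11 lists, with medians relative to that of all genes, 0.13. Lower were oxidative phosphorylation (-0.26; adjusted p = 4.00e-10), G2 and M phase targets (-0.36; 8.51e-07), DNA replication (-0.19; 0.00265) and mitochondrially encoded genes (-0.17; 0.0162). Higher were integrins and adhesion (0.30; 4.85e-06; 2 rose adjusted over the list alone), immediate early genes (0.33; 1.52e-05), extracellular matrix (0.30; 3.10e-05), muscle differentiation (0.65; 6.21e-04), YAP and SRF targets (0.17; 0.00279), the unfolded protein response (0.18; 0.0162) and hypoxia genes (0.27; 0.0223). In the order named, no call held when the correlation was estimated (adjusted p = 0.396, 0.769, 0.769, 0.769, 0.0757, 0.0757, 0.497, 0.769, 0.769, 0.769 and 0.769). By fry, which tests a list against no change, integrins and adhesion (adjusted p = 0.0162) and immediate early genes (0.0392) passed. Leaving out 1 library ended the preset call of muscle differentiation (adjusted p = 0.163 and 0.393 without quiescent shControl replicates 2 and 3, 0.148 without quiescent shFoxM1 replicate 3, 0.282 without activated shFoxM1 replicate 4), extracellular matrix (0.0653 without activated shControl replicate 2) and G2 and M targets (0.101 without quiescent shControl replicate 3). The DNA replication, YAP and SRF, hypoxia, unfolded protein and mitochondrial calls each ended without 1 of 2 or more libraries. Their adjusted p rose to at most 0.481 (DNA replication, without quiescent shFoxM1 replicate 4), 0.324 (YAP and SRF, without activated shControl replicate 3), 0.328 (hypoxia, without activated shFoxM1 replicate 3), 0.342 (unfolded protein, without the same library) and 0.426 (mitochondrial, without activated shControl replicate 2).

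Of long noncoding RNA genes, 655 were tested. H19, an imprinted RNA expressed next to Igf2, went from 977 ± 312 to 257 ± 188 FPKM in shControl cells (log2 -2.11 ± 0.56, adjusted p = 0.0132) and from 982 ± 475 to 140.0 ± 69.9 FPKM in shFoxM1 cells (-2.85 ± 0.49, 8.74e-04). Of single host genes of small nucleolar RNAs, a class that was not tested as a list, some rose, with Snhg1 at 1.05 in shControl and 1.05 in shFoxM1 cells, Snhg20 at 1.31 in shControl cells and Snhg15 at 1.08 in shFoxM1 cells. Gas5, a gene named for its level in growth-arrested cells, rose by 0.71 and 0.77, and Mir22hg changed by -1.68 in shControl cells, both genes overlapping exons of coding genes. Rab26os rose by 1.58 and 1.30, and Mir17hg, the host of the miR-17-92 cluster, by 0.98 in shFoxM1 cells. In the list of known lncRNA genes, 7 of 24 measured members rose and 6 fell (7 and 9 adjusted over the list alone) in shControl cells and 7 of 24 measured members rose and 7 fell (7 and 8 adjusted over the list alone) in shFoxM1 cells, and the set test did not call it (adjusted p = 0.799 and 0.941). On activation limma called 126 lncRNA genes in shControl cells (30 higher, 96 lower, 39 of them overlapping exons of coding genes) and 111 in shFoxM1 cells (36 higher, 75 lower, 30 overlapping). For shFoxM1 limma called 0 in quiescent cells, 0 in activated cells and 0 for the difference between responses, with 15, 15 and 14 at an unadjusted p under 0.05. In shControl cells the H19 and Gas5 calls ended without activated shControl replicate 2 (adjusted p = 0.0659 and 0.0518), and that of Gas5 also rescaled to equal sums (0.278) and with protein-coding sum scaling (0.113).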

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

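The splits for genes of the knockdown and of the difference between responses, the depth comparison, the GC trend test of the missing knockdown calls and the comparison of muscle list means in 1 library were chosen after the result was seen.

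Other splits of the same libraries tested whether chance can be excluded. On activation in shFoxM1 cells the real split alone of 35 gave 3466 gene calls, the highest other 1, in models of these libraries. Chance between cultures is not excluded by this. In shControl cells the 10 splits are too few for a share under 0.05, with 3048 genes for the real split, which was 1 of 10, and 1 for the highest other. For the knockdown and the difference between responses limma called 0 genes in the real split, a number that no split can fall below, so genes at an unadjusted p under 0.05 were counted there. By these chance cannot be excluded for the knockdown in quiescent cells (260 genes, highest other 3317, 20 of 35 splits) or in activated cells (1058, highest other 3075, 9 of 35), or for the difference between responses (433, highest other 2727, 51 of 100 drawn splits). The split with 3075 genes in activated cells, of which 599 were called, set activated shControl replicates 1 and 3 and activated shFoxM1 replicate 4 against the rest, and it points to a structure of the samples. It follows the sign of each library's GC trend, the difference between genes of high and low GC content being 0.21, 0.29 and 0.44 in these and negative in the other 4. With the trend removed and the replicate block in the model, limma called 0 knockdown genes in activated cells, with 1398 at an unadjusted p under 0.05. For gene lists, in the same models of only the libraries split, chance cannot be excluded either, on activation in shFoxM1 cells (18 lists, highest other 20, 5 of 35 splits), for the knockdown in quiescent (12, highest other 15, 8 of 35) and activated cells (7, highest other 17, 31 of 35) and for the difference between responses (11, highest other 19, 40 of 100).

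Quiescent shFoxM1 replicate 4 stood apart from its group, with a root mean square deviation 1.51 times the highest of replicates 1 to 3. It did not have lower depth, with 1.28 times the median reads of the others. Removing a trend on GC content and transcript length brought the ratio to 1.17, under the 1.5 set beforehand, so such a trend may account for part of it. A mixture with activated cells also stays open, since genes higher and lower in activated shControl cells moved by 0.358 and 0.218 of the way to activated in this library. Its muscle list mean, 0.71, was nonetheless the highest of its group, the others lying between -1.22 and 0.11, and no other explanation was tested.

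No gene was called for shFoxM1 by limma in either state. The GC and length trend as a whole cause is argued against by 0 calls in activated cells with it removed, where the smallest adjusted p was 0.455. A spread too large for 2-fold changes cannot be told apart from few such changes. The 73% of 2-fold changes recovered with real residuals (bounds set beforehand 50 and 80%) holds for 200 simulated changes, not few. Whether Foxm1 was lowered too little to lower its G2 and M targets stays open as well, because the mean of these targets relative to all genes differed by -0.28 between the activated groups with an exact permutation p of 0.343, and a p that misses the threshold does not show that they did not differ.

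Muscle differentiation genes had lower means in quiescent shFoxM1 than in quiescent shControl cells, and the size of the difference depends on single libraries. The list mean was 1.42 and 1.53 in quiescent shControl replicates 2 and 3 and -0.47 in replicate 1, which lay within the range of the shFoxM1 libraries, -1.22 (replicate 3) to 0.71. The median change relative to all genes was -1.10, and it was -0.71 and -0.69 without quiescent shControl replicates 2 and 3, -0.68 without quiescent shFoxM1 replicate 3 and -1.61 without quiescent shControl replicate 1. A trend on GC content and length is argued against, since removing it left 0.954 of the median change of the list. Differences between cultures unrelated to the hairpin stay open, because the list mean differed by -1.0 with an exact permutation p of 0.229, which shows neither a difference nor its absence. Fewer differentiated cells with shFoxM1 in either state may be another source and was not settled, the difference in activated cells being -0.41 with an exact permutation p of 0.343.

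In groups of 4 libraries, 18 of 232 measures had 1 library far from the other 3 by Dixon's ratio (95% critical value 0.83), where chance gives about 1 in 20, or 11.6. Most of the measures are genes of the same lists and libraries and are not independent. In activated shFoxM1 replicate 4, FPKM was 6.33 for Myog (others 0.05 to 0.97), 1.03 for Myh3 (0.04 to 0.17), 1.49 for Actc1 (0.19 to 0.41), 3.22 for Ttn (0.06 to 0.57) and 1.16 for Ryr1 (0.04 to 0.08). In activated shFoxM1 replicate 3 it was 4.02 for Myf5 (14.37 to 15.04), 268.7 for Cox5a (236.9 to 242.3), 2.98 for Egr3 (0.91 to 1.13) and 4.65 for Zfp36 (6.15 to 6.39), and in replicate 2 it was 25.98 for Cdkn1b (19.45 to 19.8). In quiescent shFoxM1 replicate 4, FPKM was 121.7 for Ctnnb1 (155.8 to 160.8), 26.08 for Fzr1 (20.62 to 21.05) and 19.78 for Nop2 (12.83 to 13.94), and estimated reads were 3.53e+07 (2.66e+07 to 2.80e+07). In quiescent shFoxM1 replicate 3 it was 85.84 for Dusp1 (43.57 to 48.45) and 40.3 for Thbs2 (30.27 to 31.84), and in replicate 2 it was 6.21 for Nkd2 (11.94 to 13.05) and 18.21 for Ier2 (21.63 to 21.92).

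By fry, activation responses of integrins and adhesion (adjusted p = 0.0162) and immediate early genes (0.0392) differed with shFoxM1. Camera with estimated correlation gave 0.0757 for both. Fry does not subtract the median of all genes, which was 0.13.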

How the results depend on the processing

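Removing the GC and length trend, scaling to the sum of protein-coding genes, combining that trend with the replicate block, leaving out libraries for the lists and averaging the knockdown over both states were chosen after the result was seen. Of 218 results for single genes named in the text, 133 were called, of which 118 kept their direction and their call in every alternative run for single genes (stricter thresholds were run for counts alone), 15 lost the call in at least 1 and 0 reversed. Of the 85 not called, 40 were called in at least 1 alternative, 28 of them with array weights alone, and 37 changed sign in at least 1. Depth limits genes near 0 FPKM. The 3 or 4 libraries of a group limit the knockdown comparisons, with 64 to 73% of 2-fold changes recovered among 200 simulated changes.

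The counts of genes called on activation in shControl and shFoxM1 cells were 1590 and 1982 at an adjusted p below 0.01 and 1270 and 1075 for changes of at least 2-fold, since these thresholds are stricter. The lncRNA counts were 32 and 43, and 50 and 29, at the same thresholds, 54 and 50 for genes of at least 5 FPKM, 245 and 298 with shFoxM1 libraries 1 to 3 only, and 180 in shFoxM1 cells with no filter. Shared activation calls, higher and lower, were 556 and 577 at the stricter p, 364 and 460 at 2-fold, 299 and 808 rescaled to equal sums and 555 and 2220 with protein-coding sum scaling, and 1920 lower genes were shared with shFoxM1 libraries 1 to 3 only. With no filter on low values limma called 4 knockdown genes in quiescent and 1 in activated cells. Array weights gave 9544 and 7273 genes on activation, 2564 and 4896 for the knockdown in quiescent and activated cells, 2663 for the difference between responses and 5461 for the averaged knockdown. They gave 516, 411, 218, 157 and 95 lncRNA genes in the order of the comparisons, 2736 and 3261 shared activation calls, 409 and 299 shared knockdown calls, and Foxm1 called at -0.65 in quiescent and -1.20 in activated cells. The weights gave quiescent shControl replicate 2 a value of 53.7 against 5.27 for the next library, and their fit did not converge. The gene lists called were 0 in all 5 comparisons with an estimated correlation, and by fry 22 and 22 on activation in shControl and shFoxM1 cells, 0 and 0 for the knockdown and 2 for the difference between responses. For the knockdown in activated cells 11 lists were called with quantile normalization and 12 with protein-coding sum scaling. The cause was not tested for any of these but the thresholds.

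Leaving out 1 library gave 1896 to 4341 genes on activation in shControl and 2714 to 4896 in shFoxM1 cells, the lowest without quiescent shControl replicate 2 and quiescent shFoxM1 replicate 3 and the highest without quiescent shFoxM1 replicate 4 in both. Knockdown counts were 0 to 19 in quiescent cells, 0 in activated cells, 0 for the difference between responses and 0 to 9 averaged over both states, the calls all arising without quiescent shControl replicate 1 or 2. Foxm1 ranged from -0.81 to -0.22 in quiescent and from -1.35 to -0.95 in activated cells. Lists called numbered 17 to 21 and 16 to 19 on activation, 5 to 12 and 6 to 13 for the knockdown in quiescent and activated cells and 8 to 14 for the difference between responses. Replicate numbers were not treated as pairs, since the labels give them no meaning. Of 19 pairs of the same number, 8 deviated together with r over 0.1, and pairing was to need all (range -0.229 to 0.381). The 4 quiescent and activated shFoxM1 pairs had r of 0.381, 0.0888, 0.251 and 0.234. Pairs across hairpins had -0.229 to 0.35, so a shared source for some stays open. Of 14 libraries, 4 correlated best with one of their own number. With the replicate block limma called 3983 and 4167 genes on activation and 0 for each knockdown comparison.

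With protein-coding sum scaling, Cdkn1a was -0.052 on activation in shFoxM1 cells, and Fzr1 was 0.061 and Cdkn1b 0.034 for shFoxM1 in quiescent cells, and Mki67 was 0.072 and Cdkn1b 0.021 for shFoxM1 in activated cells. With shFoxM1 libraries 1 to 3 only, Ccnb1 was -0.032, Plk1 -0.089, Cdk1 -0.15, Cdkn1b 0.087, the G2 and M list -0.045 and the DNA replication list -0.029 for shFoxM1 in quiescent cells, and Mki67 was 0.24, Cdk1 0.067, Cdkn1a -0.0074 and the DNA replication list 0.027 for shFoxM1 in activated cells, and Plk1 was 0.19, Cdk1 0.22 and the DNA replication list 0.070 for the difference between responses. Rescaled to equal sums, Fzr1 was 0.036 and Cdkn1b 0.012 for shFoxM1 in quiescent cells, and Axin2 was 0.012, Ccnb1 0.12, Myf5 0.19, Mki67 0.40, Cdk1 0.33, Cdkn1b 0.32, Ndufa1 0.075, Cox7c 0.11, Ndufa2 0.20, Ndufv2 0.20, Cdc25b 0.077, Cenpa 0.097 and Ccnb2 0.097 for shFoxM1 in activated cells, and Mki67 was 0.19, Ccnb1 0.015, Plk1 0.30, Cdk1 0.24 and Cdkn1b 0.31 for the difference between responses. Under median-of-ratios scaling, Fzr1 was 0.024 for shFoxM1 in quiescent cells, and Fzr1 was -0.053 and Plk1 -0.083 for shFoxM1 in activated cells, and Fzr1 was -0.078 for the difference between responses. Under quantile normalization, Fzr1 was 0.012 and Cdkn1b 0.012 for shFoxM1 in quiescent cells, and Fzr1 was -0.021 and the mitochondrially encoded list 0.082 for shFoxM1 in activated cells, and Fzr1 was -0.034 and the mitochondrially encoded list 0.16 for the difference between responses, and the oxidative phosphorylation list was -0.042 on activation in shFoxM1 cells. With array weights, Fzr1 was 0.052 for shFoxM1 in quiescent cells, and Fzr1 was -0.16, Mki67 0.14, Plk1 -0.032, Cdkn1a -0.24 and Cdkn1b 0.045 for shFoxM1 in activated cells, and Fzr1 was -0.21 and Cdkn1b 0.093 for the difference between responses. After removal of the GC and length trend, Fzr1 was 0.11 and the Wnt list 0.022 for shFoxM1 in quiescent cells, and Fzr1 was -0.017 for shFoxM1 in activated cells, and Fzr1 was -0.13 for the difference between responses. After the same removal with the replicate block, Fzr1 was 0.13 for shFoxM1 in quiescent cells, and Fzr1 was -0.00048, Plk1 -0.040 and Cdkn1a -0.083 for shFoxM1 in activated cells, and Fzr1 was -0.13 for the difference between responses. In the model with the replicate block alone, Cdkn1b was 0.043 for shFoxM1 in quiescent cells, and Mki67 was 0.20, Plk1 -0.058 and Cdkn1a -0.075 for shFoxM1 in activated cells. At a pseudocount of 0.1, Myog was -0.14 for the difference between responses. Scaling shifts all genes of a comparison together. For shFoxM1 in activated cells the median of all genes was 0.11 as deposited, 0.39 rescaled to equal sums, 0.20 with protein-coding sum scaling, -0.0027 with median-of-ratios scaling and 0.016 with quantile normalization, and for the difference between responses it was 0.13, 0.39, 0.17, -0.0075 and 0.0076, so reversals under these scalings are in part a shift of all genes. The cause of the other reversals was not tested.

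Leaving out 1 library at a time turned the sign of some values not called or, for lists, called at the preset correlation alone, with these ranges. Cdkn1a from -0.65 to 0.0088 on activation in shControl cells. Myf5 from -0.46 to 0.098 on activation in shFoxM1 cells. Apc from -0.11 to 0.47, Ctnnb1 from -0.053 to 0.15, Axin2 from -0.078 to 0.30, Ccnb1 from -0.19 to 0.40, Fzr1 from -0.083 to 0.062, Mki67 from -0.22 to 0.79, Plk1 from -0.089 to 0.51, Cdk1 from -0.15 to 0.23, Cdkn1b from -0.15 to 0.087, the G2 and M list from -0.11 to 0.40, the DNA replication list from -0.029 to 0.33 and the Wnt list from -0.15 to 0.054 for shFoxM1 in quiescent cells. Myf5 from -0.38 to 0.18, Fzr1 from -0.094 to 0.27, Mki67 from -0.30 to 0.24, Plk1 from -0.044 to 0.19, Cdk1 from -0.45 to 0.11, Cdkn1a from -0.15 to 0.40, the Wnt list from -0.051 to 0.15 and the DNA replication list from -0.26 to 0.056 for shFoxM1 in activated cells. Fzr1 from -0.091 to 0.28, Apc from -0.046 to 0.53, Mki67 from -0.83 to 0.17, Plk1 from -0.45 to 0.14, Cdk1 from -0.50 to 0.060, Ccnd1 from -0.011 to 0.45, Cdkn1b from -0.18 to 0.057, Myog from -0.044 to 1.29 and the mitochondrially encoded list from -0.54 to 0.074 for the difference between responses. The cause was not tested.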

Other observations

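Some lists cover other cell types or states. Of 7 measured fibroblast markers, 3 rose and 3 fell on activation in shControl cells and 2 rose and 3 fell in shFoxM1 cells (the same counts adjusted over the list alone). Examples in shControl cells were the receptor Pdgfrb, lower at -2.17 ± 0.31, and the surface protein Ly6a, higher at 1.62 ± 0.30, and in shFoxM1 cells the chemokine Cxcl12, lower at -1.35. Relative to all genes, the median and the mean of the fibroblast list differed in sign in shFoxM1 cells but not in shControl cells. Of 4 adipocyte markers 1 rose and 2 fell in each kind of cell (the same counts adjusted over the list alone), with lipoprotein lipase (Lpl) at -1.86 and -2.46 and Pparg, the adipocyte regulator, at 1.20 and 0.98. The Pparg call in shControl cells ended when libraries were rescaled to equal sums (adjusted p = 0.0513). The macrophage marker Cd68, a lysosomal protein that other cells also hold, rose by 2.03 and 1.28, and its call in shFoxM1 cells ended without quiescent shFoxM1 replicate 1 (0.0524) or 2 (0.0548), activated shFoxM1 replicate 1 (0.0669) or 3 (0.0545), with shFoxM1 libraries 1 to 3 only (0.0605) or with no filter on low values (0.064). Of 2 macrophage markers 1 rose and 0 fell and of 1 epithelial and endothelial marker 1 rose, in each kind of cell. Osteogenic markers counted 0 rose and 0 fell of 5 in shControl and 1 rose and 0 fell of 5 in shFoxM1 cells (unchanged over the list alone), where fry called the list higher (adjusted p = 0.0364) and camera did not call it (0.231 at the preset correlation, 0.495 with it estimated).

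Some lists, most of them of stress and metabolism, were not called on activation by camera at the preset correlation. In shControl cells these were p53 targets (5 rose and 4 fell of 25 (5 and 6 adjusted over the list alone); adjusted p = 0.985), glycolysis (4 rose and 2 fell of 17 (4 and 2 adjusted over the list alone); 0.315), hypoxia (1 rose and 4 fell of 18 (1 and 4 adjusted over the list alone); 0.161), the unfolded protein response (0 rose and 1 fell of 19 (0 and 0 adjusted over the list alone); 0.686), heat shock (3 rose and 1 fell of 15 (3 and 1 adjusted over the list alone); 0.133), autophagy and lysosome (0 rose and 5 fell of 26 (0 and 5 adjusted over the list alone); 0.128), inflammation (1 rose and 4 fell of 17 (1 and 4 adjusted over the list alone); 0.278) and mitochondrially encoded genes (0 rose and 1 fell of 13 (0 and 1 adjusted over the list alone); 0.906). In shFoxM1 cells the counts were 7 rose and 3 fell of 25 (7 and 3 adjusted over the list alone) for p53 targets, 3 rose and 2 fell of 18 (3 and 2 adjusted over the list alone) for hypoxia, 2 rose and 0 fell of 19 (1 and 0 adjusted over the list alone) for the unfolded protein response, 5 rose and 0 fell of 15 (5 and 0 adjusted over the list alone) for heat shock, 2 rose and 5 fell of 26 (2 and 5 adjusted over the list alone) for autophagy, 2 rose and 4 fell of 17 (2 and 4 adjusted over the list alone) for inflammation, 0 rose and 2 fell of 13 (0 and 0 adjusted over the list alone) for mitochondrially encoded genes and 1 rose and 2 fell of 7 (1 and 2 adjusted over the list alone) for inhibitors of cyclin-dependent kinases. Of these, fry called autophagy and lysosome (adjusted p = 0.0101) and inflammation (0.0279) lower in shControl cells, and heat shock (0.00929) higher and the kinase inhibitors (0.0488) lower in shFoxM1 cells. Taken relative to all genes, median, mean and camera's direction did not all agree in sign for p53 targets, the unfolded protein response, mitochondrially encoded genes, the kinase inhibitors and the known lncRNA list in shControl cells and for hypoxia and the kinase inhibitors in shFoxM1 cells. The nuclear RNA Malat1 was at 6300.1 ± 923 FPKM in quiescent and 1637 ± 236 FPKM in activated shControl cells, and at 6767 ± 4436 and 1989 ± 93.6 FPKM in shFoxM1 cells, with quiescent shFoxM1 libraries from 1177 to 12020 FPKM. Of 49585 genes in the table, 25170 were at 0 in all libraries.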
